A study of Homo sapiens with 6 samples.

How the data were processed

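RNA was sequenced from Nthy-ori 3-1 cells, a line derived from normal human thyroid follicular epithelium and immortalised with SV40 large T antigen. There were 6 libraries in 2 groups of 3. The cells of one group had been kept for 27 days in 2.5 µM decabromodiphenyl ether (BDE209), a fully brominated diphenyl ether flame retardant, and those of the other for as long in an equal volume of its solvent, dimethyl sulfoxide (DMSO). Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

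The deposited files give 1 FPKM value (fragments scaled to transcript length and to the total of the library) per gene and library, to 2 decimals, with human Ensembl gene identifiers, per the file headers. Per the labels' protocols, total RNA was checked by NanoDrop and agarose gel and libraries followed the standard Illumina procedure. Per the submitters' processing notes, the tools were Bowtie 0.12.2, Bowtie2 and RSEM, and the genome builds mm8 and mm10. Those are mouse builds, while the cells and the identifiers are human; a human build, the role of each tool, strand use and the treatment of reads that match several genes are not given in the sources used here. Reads of near-identical genes, and of overlapping or antisense genes, may therefore have been split or merged.

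Each file had 16614 rows. The 40 rows of 20 identifiers that were listed 2 times were left out, which left 16574 genes; 16535 of them matched a symbol in the reference table of gene names and 39 did not. Of the 16574 genes, 333 were listed at 0 in every library. Transcript length and GC content were looked up by identifier in GENCODE v29 (GRCh38), which is not stated to be the annotation the authors used, and were found for 99.5% of the genes tested. No coordinates are given, since no human build is named.

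FPKM are not counts, so limma 3.58.1 in R 4.3.3 was run on log2(FPKM + 1) with its trend and robust options, over the 11223 genes with an FPKM of at least 1 in 3 or more libraries. The fit held the treatment alone, without a block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Differences are BDE209 minus DMSO on the log2(FPKM + 1) scale, which understates the change of genes with low values. Before the data were examined, 33 gene lists were fixed from general knowledge of thyroid cells, of xenobiotic exposure and of stress and growth pathways. The 29 lists with 5 or more tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists. Camera compares a list with the other genes. The estimated correlation was run as an alternative, as was fry, which asks whether the genes of a list move on balance in one direction. With an estimated correlation, camera tests on the residual degrees of freedom of the libraries, which are few here. A call that it misses is therefore weak evidence against a change. No member of the list of 13 mitochondrially encoded genes was analysed here. The parafollicular C cell, endothelial and immune lists had 0, 2 and 1 tested members, and are given as single values.

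The rule for naming genes was also fixed before the data were examined: the largest changes among called genes, the thyroid hormone receptor genes THRA and THRB, and from each list up to 4 called members or, where fewer than 2 were called, the 2 tested members with the smallest p. No gene was called, so list members are given as values. Further genes were named after their values were seen: the 10 largest positive and 10 largest negative differences of a fit on replicates 1 and 3 alone, and the 10 smallest p-values of a fit with the replicate number as a block. Genes known only by a clone or locus number were not named, and a few genes that these rules would name are not reported here. COL1A1, OASL, CYP1A1, PTPRC, the follicular genes TG, TSHR and PAX8, and the genes and gene families that stand only in the closing parts were also named after their values were seen. THRB lies under the filter. Its values come from the exact permutation test over all arrangements of the 6 libraries and from limma without a filter. For the alternative settings, THRB was added to the genes of each filtered fit.

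The replicate numbers pair the samples. In the deviations from the group means, DMSO and BDE209 libraries with the same number correlated across genes at 0.738, 0.875 and 0.824 for replicates 1, 2 and 3, and each library correlated best with the one that shared its number. The labels do not say what the numbers share. Values from the fit with the block are given beside a list, or a gene tested over all genes, where they change its call. Calls of members adjusted over the list alone are mostly given with the block as a total only.

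Absolute sequencing depth is unknown, since FPKM carry no counts. The spacing of low values gives a rough relative depth: with DMSO replicate 1 as the reference, 0.998 for DMSO replicate 2, 0.625 for DMSO replicate 3, 1.00 for BDE209 replicate 1, 1.04 for BDE209 replicate 2 and 0.782 for BDE209 replicate 3. It was read from 89 to 118 genes per library, of which 19.8% to 33.3% lay within 0.1 log2 units of the step, so it is an estimate only.

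The code was tested on simulated data with the means and replicate shifts of these libraries, over 11223 genes with 100 genes changed 2-fold and 100 changed 4-fold, all drawn from genes with a mean FPKM of at least 5. For BDE209 against DMSO without the block, 20% of the 2-fold and 76% of the 4-fold changes were recovered, with 0 false calls. With the block, 79% and 97% were recovered, with 4 false calls. For replicates 1 and 3 alone, 66% and 94% were recovered, with 1 false call. Camera at either correlation and fry with the block each called 3 of 3 shifted lists of random genes and 0 of 27 unshifted ones. These lists carried no correlation between genes, and each gene of a shifted list moved by 1 log2 unit. The lists called in the real data had medians of at most 0.81 in size over all 6 libraries. Camera was simulated without the block only, so its recovery with the block or for smaller shifts is not shown.

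The alternatives fixed before the data were examined were quantile normalization, median centring, limma without its trend, an ordinary linear model per gene, no filter, a minimum FPKM of 5, a pseudocount of 0.1, a minimum fold of 2, the replicate block, each library left out in turn and, for lists, an estimated correlation, fry and camera on ranks. Others were chosen after seeing the data, because both replicate 2 libraries stood apart: each pair of replicates alone, without and with the block, the block without the robust option, removal of the trend on transcript length (loess, span 0.5) together with the block, and, for lists, the estimated correlation or fry with the block and the estimated correlation on replicates 1 and 3. A change of sign of a list was counted as a reversal only where the list was called in either setting, a rule set after its values were seen; 47 other sign changes of lists lay between values that both missed the threshold. An interaction term for replicate 2 against replicates 1 and 3, in limma and camera, and each replicate set apart with the block were also added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.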

Results

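Transcript levels were measured by RNA sequencing in 6 libraries of Nthy-ori 3-1 thyroid cells, 3 kept for 27 days in 2.5 µM BDE209 and 3 kept as long in its solvent DMSO. BDE209 is a flame retardant that persists in the environment and resembles thyroid hormone in outline. The series asks how BDE209 acts on thyroid cell growth and tumour formation, and names the thyroid hormone receptor beta as the protein it acts through. The FPKM of a library summed to 596725, 819086 and 580098 in DMSO replicates 1, 2 and 3 and to 586204, 829739 and 567810 in BDE209 replicates 1, 2 and 3. Between 14630 and 14914 genes per library were listed above 0. Depth in fragments is not known, since FPKM carry no counts.

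Replicate 2 stood further from the other replicates than BDE209 stood from DMSO. Among replicates 1 and 3 the treatment separated the libraries more than the number did. There, libraries correlated at 0.9956 (DMSO) and 0.9942 (BDE209) within a treatment, against 0.9899 (replicate 1) and 0.9895 (replicate 3) within a number. The first principal component held 80.4% of the variance and set both replicate 2 libraries apart, and the second, with 11.1%, set BDE209 apart from DMSO in replicates 1 and 3 alone, as the plot of library components shows. Ribosomal protein genes took 31.3% of the summed FPKM in DMSO replicate 2 and 31.8% in BDE209 replicate 2, against 18.8% to 21.3% in the other libraries. The shift of replicate 2 followed transcript length, with a median of 0.33 log2 units over the shortest and -0.37 over the longest of 4 equal groups of genes. The list of nuclear oxidative phosphorylation genes stood higher there, by a median of 0.60 (camera adjusted p = 2.31e-09; 0.479 with an estimated correlation). The mesenchymal and matrix list stood lower, at a median of -0.69 (adjusted p = 0.00101; 0.479 with an estimated correlation), and COL1A1, the main fibrillar collagen, read 863 and 787 FPKM in the replicate 2 libraries against 2270 to 2560 in the others.

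**Figure D1:**
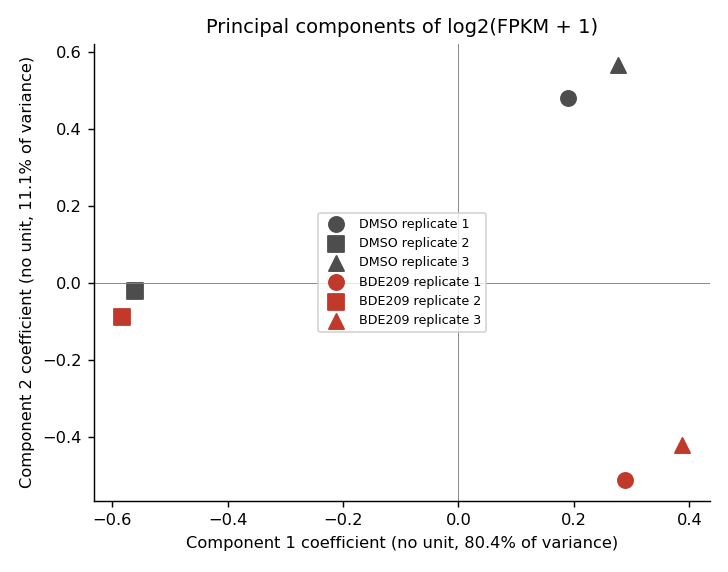
Coefficients of the 6 libraries on the first and the second principal component of log2(FPKM + 1), by group and replicate number. Component 1 (80.4% of the variance) sets both replicate 2 libraries apart and component 2 (11.1%) sets BDE209 apart from DMSO in replicates 1 and 3.

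In cells kept in BDE209, interferon-stimulated genes rose as a group in all 3 replicates, with medians of 0.30, 0.41 and 0.30 log2 units in replicates 1, 2 and 3. The list of inflammatory NF-kB genes rose much further, by medians of 1.24 and 1.09, in replicates 1 and 3, but stood at -0.02 in replicate 2. Genes of glycolysis and hypoxia rose likewise, by 0.52 and 0.57 in replicates 1 and 3, and stood at -0.07 in replicate 2. Genes of cholesterol synthesis fell, with medians of -0.26 and -0.36 in replicates 1 and 3 and 0.03 in replicate 2, and genes of mitosis fell with -0.23, -0.26 and 0.01. These lists were called by camera at its preset correlation (8 of 29 lists), and none was called with an estimated correlation (0 of 29). In the NF-kB, glycolysis, cholesterol and mitosis lists the estimated correlation was 0.14 to 0.40. A shared movement of their genes is therefore not excluded as the reason for a call. The interferon list had one of -0.02, under the preset 0.01, so shared movement does not account for its lost call. The estimated variant also tests on few residual degrees of freedom, which lowers its power.

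No single gene passed the threshold in all 6 libraries. Limma called 0 of the 11223 genes, with 176 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. An ordinary linear model called 0, with 308 at that level, and limma without its trend called 0, with 176. With the replicate number as a block the count stayed at 0, while 1847 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0622. The 3 BDE209 values lay apart from the 3 DMSO values in 586 genes, or 5.22%; chance gives 10% for libraries that are free to trade places, and less where, as here, pairs of libraries share a shift. All 3 pairs had the same sign in 4399 genes, or 39.2%; chance gives 25% for independent pairs, which pairs 1 and 3 were not (r = 0.727), so this is no measure of agreement across all 3. Adjusted over the list alone, 5 list members were called across all lists, namely IFI6, MX1, LUM, DCN and NKD1. With the block the calls of LUM and DCN were lost.

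**Figure D2:**
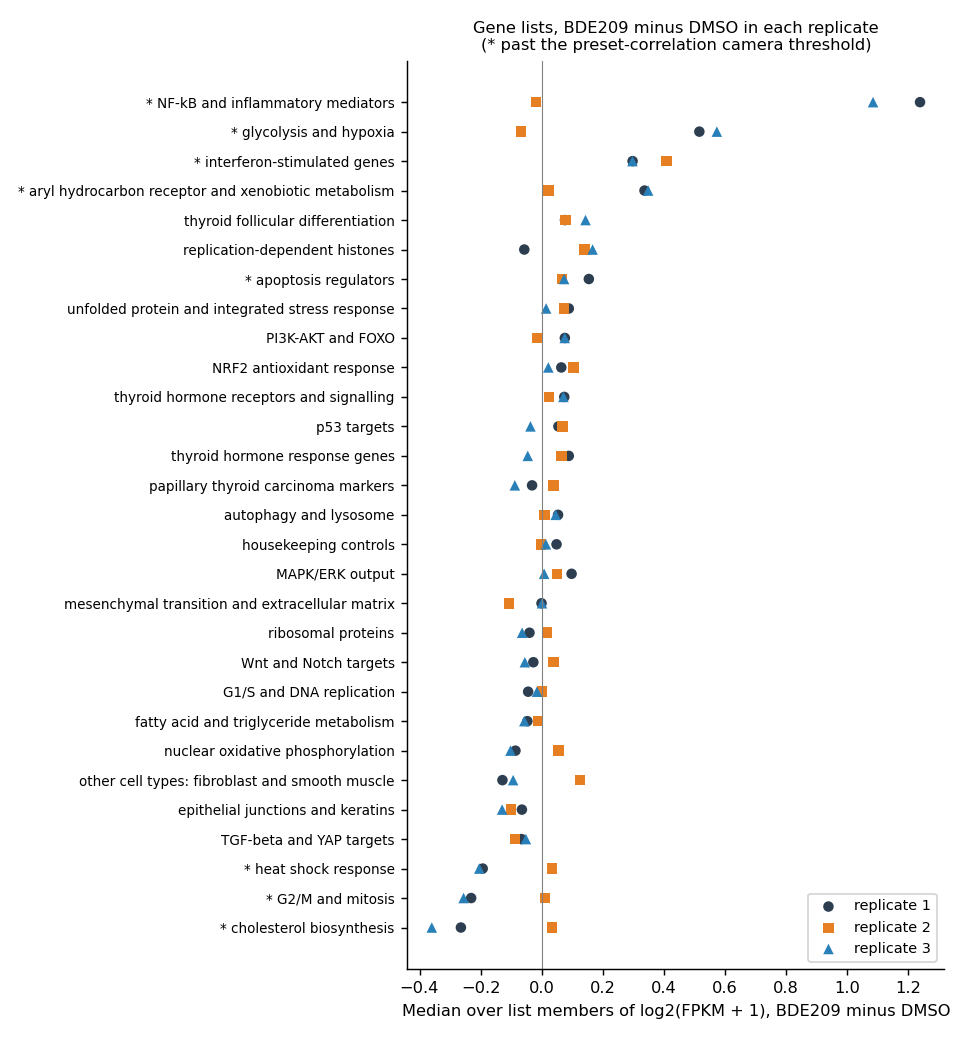
Median log2(FPKM + 1) difference, BDE209 minus DMSO, of the tested members of each of the 29 lists, with 1 point per replicate; an asterisk marks the 8 lists called by camera at its preset correlation. The medians of replicates 1 and 3 lie close together in the NF-kB list (1.24 and 1.09), while that of replicate 2 is -0.02; the interferon list is above 0 in all 3.

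The interferon list holds antiviral effectors induced by type I and II interferons. The list rose, with 15 of its 18 tested members higher in all 3 pairs (camera adjusted p = 1.15e-10), and the call was lost with an estimated correlation (adjusted p = 0.0531; 0.546 with the block and 0.248 in replicates 1 and 3 alone). It was also the only list that fry called, at an adjusted p of 0.0305, or 0.0194 with the block. IFI6, a mitochondrial protein that restrains apoptosis, went from 57.4 ± 8.22 FPKM in DMSO to 97.5 ± 4.93 in BDE209 (SD, n = 3), a log2 difference of 0.76. MX1, an antiviral GTPase, went from 1.36 ± 0.123 to 2.56 ± 0.468, a log2 difference of 0.59. Adjusted over the list alone, IFI6 and MX1 were the 2 members called, against 0 over all genes, and 14 were with the block. Among the 3 others, OASL, a homologue of antiviral enzymes, was lower in replicates 1 and 3, at 1.5 and 2.58 FPKM in DMSO and 0.86 and 0.61 in BDE209, and higher in replicate 2, at 2.96 and 6.51. A test of whether an effect differed between replicate 2 and the others was added after the pattern was seen. It has 1 library per group in replicate 2 and takes its spread from replicates 1 and 3 alone. Its variant with an estimated correlation rests on few residual degrees of freedom, so a miss by that variant says little. For the interferon list the test found no difference.

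The NF-kB list holds cytokines, chemokines and adhesion molecules of inflammation. The list rose, with a median of 0.81 over its 23 tested members (camera adjusted p = 4.24e-15; 0.286 with an estimated correlation), of which 9 were higher and 1 was lower in all 3 pairs. By the test added later, with 1 library per group in replicate 2, the effect differed between replicate 2 and the others (adjusted p = 3.97e-26), but not with an estimated correlation (0.114). IL1A, which starts inflammatory signalling, read 1.71 ± 0.537 FPKM in DMSO and 5.97 ± 2.67 in BDE209. ICAM1, by which leukocytes adhere, read 2.47 ± 1.62 and 7.82 ± 2.44. Their log2 differences were 1.30 and 1.40. In replicates 1 and 3 alone, 18 members were higher and 1 was lower, by limma at an adjusted p under 0.05.

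The glycolysis and hypoxia list holds glycolytic enzymes and targets of hypoxia-inducible factor. The list rose, with a median of 0.34 over its 27 tested members, 6 of them higher in all 3 pairs (camera adjusted p = 4.00e-12; 0.391 with an estimated correlation), and by the same added test the effect differed in replicate 2 (adjusted p = 2.60e-22), but not with an estimated correlation (0.114). CA9, a carbonic anhydrase that tracks hypoxia, read 7.26, 26.68 and 9.42 FPKM in DMSO replicates 1, 2 and 3 and 42.82, 24.40 and 48.00 in BDE209. NDRG1, a stress gene of the same programme, read 98.43 to 118.52 FPKM in DMSO and 135.63 to 171.01 in BDE209, a log2 difference of 0.57 that was positive in all 3 pairs. In replicates 1 and 3 alone, 18 members were higher and 0 were lower.

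The aryl hydrocarbon receptor list, enzymes that handle foreign compounds and dioxin-like ligands, rose by medians of 0.34, 0.02 and 0.35 in replicates 1, 2 and 3 (9 members; camera adjusted p = 0.00915; 0.659 with an estimated correlation). Its estimated correlation was 0.89 against the preset 0.01, so shared movement of its genes is not excluded as the reason for the call. NQO1, a quinone reductase, read 232 ± 13.8 FPKM in DMSO and 303 ± 40.1 in BDE209. CYP1B1, a cytochrome P450, read 1.37 ± 0.425 and 2.01 ± 0.486. The call was lost without DMSO replicate 2 (adjusted p = 0.422), BDE209 replicate 1 (0.162) or BDE209 replicate 3 (0.237). Leaving out any of these libraries gives the replicate 2 shift, a median of -0.49 in this list, more weight in BDE209. The call was also lost without the filter (0.0909) or with a minimum FPKM of 5 (0.0668). By the added test the effect differed in replicate 2 (adjusted p = 0.00544), but not with an estimated correlation (0.574). CYP1A1, the classical target of the receptor, lay near the filter, at 0.48 to 0.76 FPKM in DMSO and 0.92 to 1.29 in BDE209. The apoptosis list, regulators of programmed death, rose by a median of 0.09 (23 members, camera adjusted p = 0.0190, or 0.286 with an estimated correlation). BIRC3, an inhibitor of apoptosis under NF-kB control, differed by 0.86, and BMF, which promotes death, by 0.35. That call was lost without DMSO replicate 1 (adjusted p = 0.179) or BDE209 replicate 2 (0.253), without the filter (0.0909) and at a minimum FPKM of 5 (0.0699).

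The cholesterol synthesis list, enzymes and regulators under SREBP2, fell by a median of 0.18 (22 members; camera adjusted p = 6.84e-09; 0.286 with an estimated correlation). INSIG1, which holds SREBP in the endoplasmic reticulum, read 39.8 ± 6.66 FPKM in DMSO and 28.2 ± 6.23 in BDE209. MVK, mevalonate kinase, read 10.2 ± 0.879 and 7.95 ± 0.901, and was lower in all 3 pairs. The list of mitosis genes fell by a median of 0.17 (28 members; camera adjusted p = 2.26e-07; 0.465 with an estimated correlation). PLK1, a mitotic kinase, read 116 ± 4.82 and 98.2 ± 3.64, lower in all 3 pairs, and CENPE, a kinetochore motor, differed by -0.25. The heat shock list of chaperones fell by a median of 0.13 (17 members; camera adjusted p = 0.00156; 0.391 with an estimated correlation). HSPH1 and HSP90AA1, both cytosolic chaperones, differed by -0.24 and -0.27. Without BDE209 replicate 3 the heat shock call was lost (adjusted p = 0.0594). By the same added test, with the spread taken from replicates 1 and 3, all 3 effects differed in replicate 2 at the preset correlation, with adjusted p of 4.18e-08, 1.86e-06 and 0.000195, and with an estimated correlation none did (0.328, 0.836 and 0.744).

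With the block, 2 further lists were called as lower, although their medians in replicate 2 were 0.06 and 0.02. Nuclear oxidative phosphorylation genes, the respiratory chain, had an adjusted p of 0.0358 (0.186 without the block), and ribosomal protein genes one of 0.0333 (0.295 without), by camera at the preset correlation. With an estimated correlation the block fit called 0 lists, but on few residual degrees of freedom, so that result decides little. By the added test, the oxidative phosphorylation effect differed in replicate 2 (adjusted p = 0.0021), but not with an estimated correlation (0.933), and the ribosomal one did not (0.401). CYC1 and NDUFV1 of the respiratory chain differed by -0.19 and -0.09. RPL32 and RPL18, of the large ribosomal subunit, differed by -0.16 and -0.14. Without DMSO replicate 2 the ribosomal list was called in the other direction, as higher, at a camera adjusted p of 0.00494. That fit has no block and keeps the replicate 2 shift, a median of 0.90 in this list, in BDE209 alone.

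THRB, the receptor gene that the series names, stayed at low values in both groups. Its FPKM (ENSG00000151090) were 0.34, 0.19 and 0.36 in DMSO replicates 1, 2 and 3 and 0.36, 0.20 and 0.38 in BDE209, or 0.297 ± 0.0929 and 0.313 ± 0.0987 (SD, n = 3). The log2 difference was 0.02 (exact permutation p = 0.6, two-sided; the smallest that 3 against 3 allows is 0.1), under the spread between replicates. THRB was higher in all 3 pairs, by ratios of 1.06, 1.05 and 1.06, at values given to 2 decimals; the permutation test leaves the pairing out. Limma with the block and without a filter gave an adjusted p of 0.849 and a 95% interval of -0.08 to 0.11. At such low values the log2(FPKM + 1) scale shrinks differences, so the interval is not a tight bound on THRB. With a pseudocount of 0.1 and no block, the difference was 0.06 (SE 0.375). THRA (ENSG00000126351), the receptor alpha gene, was far more abundant, at 14.14, 9.83 and 15.66 in DMSO and 18.58, 10.38 and 19.06 in BDE209, or 13.2 ± 3.02 and 16.0 ± 4.88. Its log2 difference was 0.24 (SE 0.277; limma adjusted p = 1.00; 0.242 with the block), higher in all 3 pairs, and it was 0.05 without DMSO replicate 2 and 0.50 without BDE209 replicate 2. The protein, and its binding to hormone, were not measured.

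**Figure D3:**
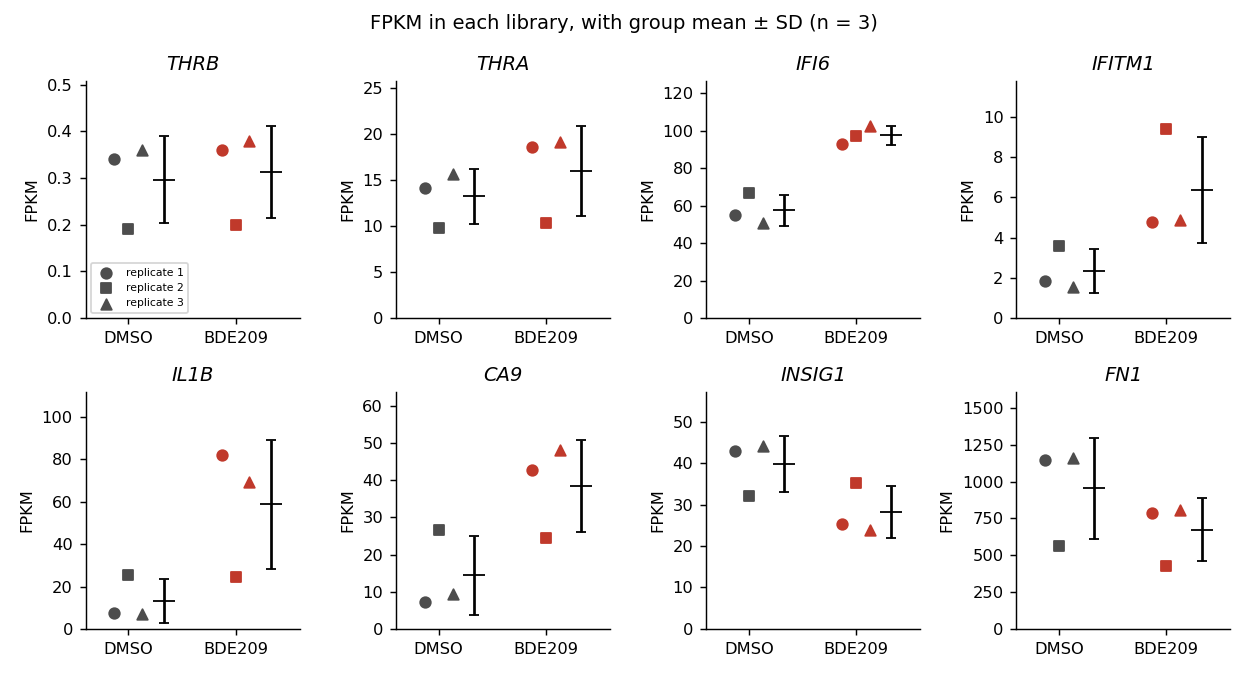
FPKM of 8 genes in each of the 6 libraries, by group, with the mean and SD of the 3 replicates; the shape of a point marks its replicate and each panel has its own scale. THRB stays between 0.19 and 0.38 in both groups, IFI6 is 54.76, 66.67 and 50.91 in DMSO and 92.87, 97.00 and 102.68 in BDE209, and IL1B and CA9 differ in replicates 1 and 3 alone.

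The lists on thyroid hormone and the thyroid were not called by camera. Receptors and signalling of the hormone had an adjusted p of 0.253 (16 tested members) and its response genes 0.561 (11 tested members). The response genes were called as lower without DMSO replicate 2, at 0.0271. Follicular differentiation had 0.295 (6 tested members of 24) and papillary thyroid carcinoma markers 0.295 (11 of 26). Adjusted over the list alone, 6 response genes were called with the block, against 0, 0 and 1 members of the receptor, follicular and carcinoma lists. Over all genes, limma on replicates 1 and 3 alone called 2 response genes higher and 2 lower. Camera looks for a common direction, so such mixed changes can escape it. Among hormone signalling genes, the integrin subunit ITGAV, a cell-surface binding site of thyroxine, differed by 0.36 and the coactivator NCOA3 by 0.16. KLF9, a direct hormone target, differed by 0.37. The follicular transcription factors HHEX and GLIS3 differed by 0.19 and 0.13. Of the carcinoma markers, the protease inhibitor TIMP1 differed by -0.31 and the receptor kinase MET by -0.27. Follicular function genes were near 0: thyroglobulin (TG) read 0.02 to 0.12 FPKM, the TSH receptor (TSHR) 0.03 to 0.08 and PAX8 0.35 to 0.49.

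The lists on growth and stress signalling were not called either. DNA replication genes had a camera adjusted p of 0.263; CDC25A, a phosphatase of S phase entry, differed by -0.17 and TYMS, thymidylate synthase, by 0.20. For p53 targets it was 0.295, with the death receptors TNFRSF10B at 0.42 and FAS at 0.24. For the NRF2 antioxidant response it was 0.252, with the reductase AKR1B10 at 0.41 and OSGIN1 at -0.30, both the same way in all 3 pairs. The unfolded protein and integrated stress response had 0.323, with DDIT3, a death-promoting factor, at 0.21 and the chaperone DNAJB9 at 0.28. MAPK/ERK output had 0.158, with its feedback phosphatases DUSP4 at 0.55 and DUSP6 at 0.36. For PI3K-AKT and FOXO it was 0.684, with the cyclin CCNG2 at 0.45. Wnt and Notch targets had 0.983; the Wnt inhibitors NKD1 and DKK1 went apart, at 0.74 and -0.49, and NKD1 was the 1 member called adjusted over the list alone.

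Of the metabolic lists, fatty acid and triglyceride metabolism had a camera adjusted p of 0.637, with the lipase inhibitor ANGPTL4 at 1.43 and ACSS2, which makes acetyl-CoA, at 0.21. Autophagy and lysosome genes had 0.272, with GABARAPL1 and WIPI1, both of the autophagosome, at 0.49 and 0.39. Replication-dependent histones had 0.252, with H2AC11 at 0.51 and H2AC8 at 0.38; histone genes are near-identical and largely without poly(A), so these values are uncertain. Housekeeping controls had 0.989, with the hypoxia-responsive PGK1 at 0.42 and TBP at -0.10. Epithelial junctions and keratins had 0.158, on 6 tested members of 24, with KRT7 and KRT18 at -0.31 and -0.17. Mesenchymal transition and matrix genes had 0.158, with the basement membrane collagen COL4A2 at -0.37. TGF-beta and YAP targets had 0.252, with the matricellular CCN2 at -0.72. The fibroblast and smooth muscle list had 0.561, with the proteoglycans LUM and DCN at 1.10 and 0.79. Both were called adjusted over the list alone, but with the block 0 members of that list were.

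Across these lists the 60 genes chosen by smallest p had SE of 0.108 to 0.706 and limma adjusted p of 1.00, and 52 of them had the same sign in all 3 pairs, which a choice by smallest p favours (39.2% over all genes). In 6 lists the median and the test had opposite signs: hormone response genes, carcinoma markers, MAPK/ERK output, Wnt and Notch targets, housekeeping controls and the fibroblast list. The mean of the fatty acid list was 0.02, against a negative median and test. Adjusted over the list alone, 65 members in 16 lists were called with the block, against 0 over all genes. The endothelial KDR and ESAM differed by 0.25 and -0.19, with values of 0.69 to 2.81 FPKM, and the lysosomal CD68 of the immune list by -0.26, at 48.2 to 73.6 FPKM, while the leukocyte gene PTPRC stayed at or under 0.02. Of the parafollicular C cell list 9 of 12 genes were listed and 0 were tested.

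The differences of replicates 1 and 3 resembled each other more than those of replicate 2, apart from groups such as the interferon genes. Across genes, which are not independent replicates, the differences of pairs 1 and 3 correlated at r = 0.727, those of pairs 1 and 2 at 0.0589 and those of pairs 2 and 3 at -0.0025. In a comparison chosen after this was seen, limma on replicates 1 and 3 alone called 764 genes, 502 higher and 262 lower, while replicates 1 and 2 alone gave 0 (8 at an unadjusted p under 0.05) and replicates 2 and 3 alone gave 0 (8). Without the block the shift of replicate 2 widens the spread in those last fits. With the block, on 1 residual degree of freedom, the counts were 3146 for replicates 1 and 3, 0 for replicates 1 and 2 (663 at an unadjusted p under 0.05) and 0 for replicates 2 and 3 (487). The 764 genes describe these 4 libraries. The largest rises were in C3, the central complement component, by 3.26 log2 units, and IL1B, an inflammatory cytokine, by 3.20. IL1B read 7.63 and 7.05 FPKM in DMSO replicates 1 and 3 and 82.07 and 69.57 in BDE209, but 25.31 and 24.56 in replicate 2. The cytokines CSF2 and IL6 rose by 2.48 and 2.17, CA9 by 2.32, ANGPTL4 by 2.13, the chemokine CXCL8 by 2.07, the secreted C1QTNF1 by 2.02 and ICAM1 by 2.01. COMMD3-BMI1, at 1.96, is a read-through transcript that shares its sequence with both of its parent genes and is uncertain. CXCL8 in replicate 2 was 639.87 FPKM in DMSO and 517.86 in BDE209, above every other library.

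Among the largest falls in the same 4 libraries were some matrix genes, although the list of mesenchymal and matrix genes was not called there (camera adjusted p = 0.236; 2 members higher and 6 lower). POSTN and COL3A1, a matricellular protein and a fibrillar collagen, fell by 1.70 each, and COL5A2, a collagen of the same fibrils, by 1.03. The chorionic gonadotropin genes CGB5 and CGB8 fell by 1.69 and 1.54, and their near-identical copies make the split of reads between them uncertain. TRHDE, which degrades thyrotropin-releasing hormone, fell by 1.23, the homeobox gene HOPX by 1.16, the cadherin CDH6 by 1.16 and the chemokine CXCL12 by 1.10. Limma's adjusted p for the genes named from these 4 libraries lay between 2.06e-05 and 0.0144.

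**Figure D4:**
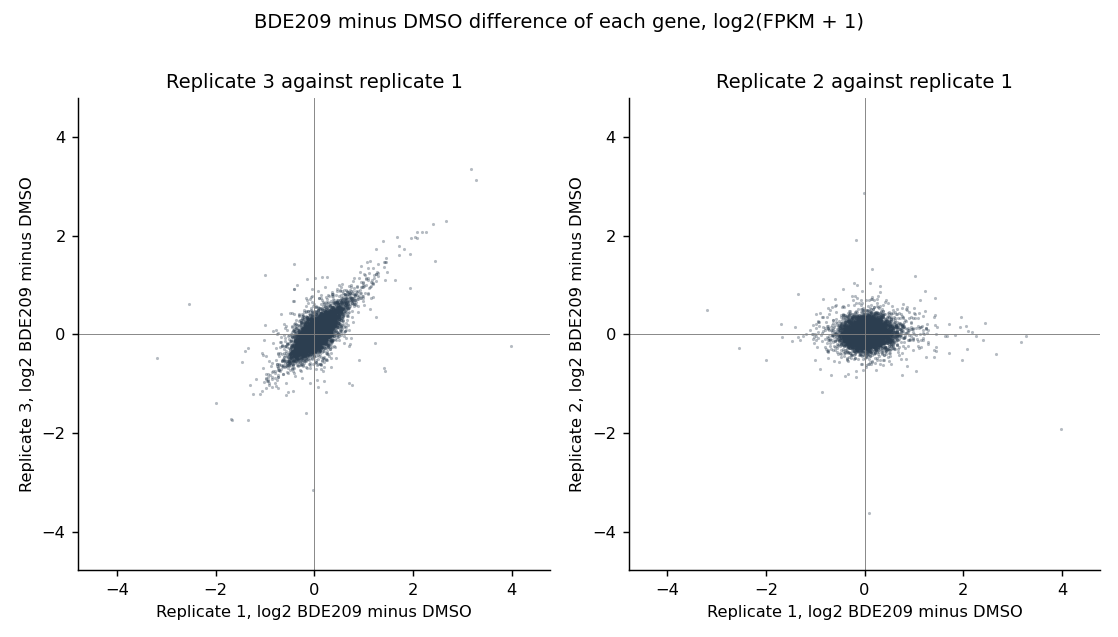
Log2(FPKM + 1) difference, BDE209 minus DMSO, of every tested gene in replicate 3 (left) and in replicate 2 (right) against that in replicate 1. The differences of replicates 1 and 3 correlate at r = 0.727 across genes, and those of replicates 1 and 2 at 0.0589.

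No gene passed the threshold in the fit with the block, which ranks genes by how alike their 3 pair differences are. The 10 with the smallest p there, named after their values were seen, had adjusted p of 0.0622 to 0.144 by limma, and their equal sign in all 3 pairs follows from that choice. First among them was IFITM1, a membrane protein that blocks viral entry, at 1.84, 3.58 and 1.57 FPKM in DMSO and 4.79, 9.40 and 4.88 in BDE209, a log2 difference of 1.13. LRRC32, which presents latent TGF-beta, differed by 1.08, BMP2, a bone morphogenetic ligand, by 0.72, THBS2, a matricellular inhibitor of vessel growth, by 0.62 and the sialic acid receptor SIGLEC15 by 0.60. NKD1 and GABARAPL1, named above, were also among them. FN1, fibronectin, a carcinoma marker, read 956 ± 342 FPKM in DMSO and 675 ± 216 in BDE209, a difference of -0.48. MMP3, stromelysin, differed by -0.52 and the tubulin gene TUBA3C, which has a near-identical copy, by -0.81.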

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

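The tests of transcript length, of depth, of swapped labels and of random error, and the comparison of replicate 2 with replicates 1 and 3, with and without the block, were chosen only after the result was seen.

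The effect of BDE209 differed between replicate 2 and replicates 1 and 3 in 69 genes (limma, a test of the difference itself), 17 with a higher and 52 with a lower effect in replicate 2. Replicate 2 supplies 1 library per group, so its libraries are assumed to vary like those of replicates 1 and 3, from which the spread comes. With the replicate block, on 1 residual degree of freedom, 1153 genes differed. C3 rose by 3.26 log2 units in replicates 1 and 3 and differed by -0.15 in replicate 2, and IL1B by 3.20 and -0.04, with adjusted p of 0.000401 and 0.00111 for the difference. COL3A1 fell by 1.70 and differed by 0.21 in replicate 2 (adjusted p = 0.00443). SULT1A3 also stood out (adjusted p = 0.000401), but it was listed at 0 in BDE209 replicate 2 and at 11.24 to 15.74 FPKM elsewhere, and a near-identical gene makes it uncertain. There are 3 ways to set 1 replicate apart, too few for a share under 0.05; the real choice gave 69 and the highest other gave 0. Those other counts say little, because setting replicate 1 or 3 apart leaves replicate 2 in the spread: 5 and 11 genes had an unadjusted p under 0.05, or 111 and 190 with the block. For the 764 genes of replicates 1 and 3 alone, 1 of the 3 splits of the 4 libraries gave as many, again too few; the highest other gave 2.

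The genes called in replicates 1 and 3 differed less in replicate 2, with medians of 0.03 for the higher and -0.01 for the lower against 0.56 and -0.48, while the interferon list rose there as well (0.41). Swapped labels in replicate 2 would give opposite signs only to genes that carry an effect there. Of the genes called in replicates 1 and 3, 55.4% had the same sign in replicate 2 (binomial 95% interval 51.8% to 58.9% with genes taken as independent), against 52.8% over all genes. With such small medians in replicate 2, these signs cannot decide on a swap. A swap would exchange whole libraries, and the interferon list rose in all 3 replicates (medians 0.30, 0.41 and 0.30). That argues against a swap, as far as this list carries an effect in replicate 2. Random error that hid an effect as large as in the other pairs would have added to the SD over genes and left the covariance with them in place. The SD was 0.166 in pair 2 against 0.264 and 0.267 in pairs 1 and 3, and the covariance of pair 1 was 0.00258 with pair 2 against 0.0512 with pair 3, which argues against hidden effects, though not against larger error as such. A candidate explanation is that the DMSO cells of replicate 2 already stood part of the way to the treated level. Over the 69 genes more than 1 log2 unit higher in pair 1, DMSO replicate 2 exceeded DMSO replicate 3 by a median of 0.544 (bootstrap 95% interval 0.248 to 0.864), against 1.25 for the effect in pair 1, 0.04 in pair 2 and -0.09 for all genes in the same contrast. That interval, with genes taken as independent, lies below a full rise and spans slight and larger partial ones, so a partial rise stays open. Raised controls alone would leave BDE209 replicate 2 at the treated level. Of 2 genes picked after their values were seen, C3 fell short there, at 7.12 FPKM against 24.88 and 26.08 in BDE209 replicates 1 and 3. CXCL8 lay above, at 517.86 against 218.87 and 185.86. These 2 do not stand for the 69 genes. Over the 69, the median excess of DMSO replicate 2 was 0.537 with the length trend removed, against an effect of 1.22 in pair 3. The shift of both replicate 2 libraries had a median of 0.45 in the NF-kB list, which rose with BDE209. That shift went against the treated direction in the mitosis list (0.36), which fell, and the aryl hydrocarbon receptor list (-0.49), which rose. No biological explanation was tested.

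Both replicate 2 libraries also stood apart from the rest in their levels, with 410 genes more than 1 log2 unit higher and 368 lower, and the shift in DMSO correlated with that in BDE209 at r = 0.875 across genes. Lower depth is argued against, since the smaller relative depth of these libraries was 0.998. A trend on GC content as the cause is argued against too, since 85.5% of the shifted genes remained shifted after its removal. Transcript length may account for part of it: of 4 equal groups of genes by length, that with the shortest transcripts stood 0.33 higher, that with the longest stood at -0.37, and 39.1% of the shifted genes remained so once the trend was removed. The trend explained 28.2% of the variance of the shift, and what made length matter, such as fragment size, RNA integrity or library handling, was not measured. The labels name no batch, and no biological explanation was tested.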

How the results depend on the processing

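The fits on chosen replicates, the block without the robust option, the length trend and the block combined with another list test were chosen only after the results were seen. Limma called 0 genes under quantile normalization, median centring, no trend, an ordinary linear model, no filter, a minimum FPKM of 5, a pseudocount of 0.1, a minimum fold of 2, the replicate block and the length trend removed with the block, with 110 to 1932 genes at an unadjusted p under 0.05 where that was counted. Leaving out 1 library gave 51 to 866 such genes (51 without BDE209 replicate 1, 52 without DMSO replicate 1, 54 without DMSO replicate 3, 70 without BDE209 replicate 3, 405 without DMSO replicate 2 and 866 without BDE209 replicate 2, against 176 with all), 0 to 1 genes changed and 0 to 1 higher: without BDE209 replicate 2, C1QTNF1 was higher (adjusted p = 0.0459). Replicates 1 and 3 alone gave 764 genes (502 higher, 262 lower), and with the replicate block 3146 (1580 higher, 1566 lower), on 1 residual degree of freedom per gene; replicates 1 and 2 or 2 and 3 alone gave 0 with and without it. The lists called, 8 by camera, were 0 with an estimated correlation, 1 by fry, 10 with the replicate block, 0 with the block and an estimated correlation, 1 with the block and fry, 0 with replicates 1 and 3 and an estimated correlation, and 8 to 11 with 1 library left out. Beyond adding the respiratory chain and ribosomal lists, the block changed no other call. THRA was called in 1 setting, replicates 1 and 3 with the replicate block (0.32; adjusted p = 0.00146; 0.0707 to 1.00 in the others), and its difference ranged from 0.05 to 0.50 with 1 library left out. THRB changed sign with median centring (-0.002227) and with the length trend removed and the block (-0.01571), and ranged from -0.04248 to 0.08187 with 1 library left out; it was called in no setting. With 1 library left out, GLIS3 ranged from -0.004814 to 0.31, MMP3 from -1.19 to 0.18, RPL18 from -0.39 to 0.12, RPL32 from -0.425 to 0.09274 and the adjusted p of the ribosomal list from 2.80e-05 to 0.389; that list was called as higher without DMSO replicate 2 (0.00494) and as lower without DMSO replicate 1, DMSO replicate 3 or BDE209 replicate 2. H2AC8 was -0.13 with replicates 1 and 2 alone, with and without the block. These were the 5 named genes of 85 and the 1 list of 29 that reversed, beside THRB. Lists missed with all libraries were called in some settings. Mesenchymal genes were lower without DMSO replicate 2 (0.000304), BDE209 replicate 1 (0.0173) or BDE209 replicate 3 (0.00505), and hormone response genes without DMSO replicate 2 (0.0271). Histones were higher without DMSO replicate 2 (0.0311) or BDE209 replicate 1 (0.00173), and PI3K-AKT genes without BDE209 replicate 2 (0.0136). Nuclear oxidative phosphorylation was lower without DMSO replicate 1 (0.00613), DMSO replicate 3 (0.000461) or BDE209 replicate 2 (6.20e-06), as it was in replicates 1 and 3 alone (0.0039). Epithelial genes were called as lower without BDE209 replicate 3 (0.0215) and with no filter (4.96e-05). The latter call includes members with low values, since only 6 of 24 passed the filter. Without the block, leaving out 1 library gives the groups unequal shares of the replicate 2 shift. Its medians were 0.90, 0.60 and 0.42 in the ribosomal, oxidative phosphorylation and histone lists. In the mesenchymal, hormone response, PI3K-AKT and epithelial lists they were -0.69, -0.64, -0.51 and -0.27. Each call gained with 1 library left out had the sign this imbalance gives, and cannot be told apart from it. The cause of the other changes was not tested. Depth is unknown in absolute terms, so no floor can be given for THRB or for other genes near 0.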

Other observations

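The gene families here, and the weighing of the block swaps against the real labels, were chosen only after their results were seen; the counts over the splits of the 6 libraries were planned.

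The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For genes called by limma the real split gave 0 and the highest other gave 0, so all 10 gave as many. For lists called by camera it gave 8 and the highest other 8, so 2 of the 10 gave as many; the other was DMSO replicates 1 and 3 with BDE209 replicate 1 against the rest. The split that joined both replicate 2 libraries with DMSO replicate 1 gave 3823 genes at an unadjusted p under 0.05, against 176 for the real one, which points to the structure of the samples by replicate number. With the block, 1 of the 4 ways to swap labels within pairs gave as many genes at an unadjusted p under 0.05 as the real 1847, again too few ways; swapping replicate 2 gave 1411, and the other swaps gave 80 and 52.

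Of 6 gene families looked at, class I HLA genes, which present antigens, were higher by medians of 0.41, 0.06 and 0.45 in replicates 1, 2 and 3 (5 genes; camera adjusted p = 0.000553; 0.131 with an estimated correlation). HLA-B went from 17.12, 13.29 and 14.95 FPKM in DMSO to 47.47, 15.37 and 43.37 in BDE209, and the reads of HLA genes are hard to assign. Guanylate-binding proteins, interferon-induced GTPases, were higher by 0.62, 0.22 and 0.47 (3 genes; 0.00188; 0.131 estimated). Metallothioneins, which bind metals, differed by 0.46, -0.07 and 0.29 (5 genes; 0.0471; 0.329 estimated). The chorionic gonadotropin genes were lower, by medians of -0.41, -0.14 and -0.79 (5 genes; 0.00153; 0.329 estimated). Collagens (23 genes) and amino acid carriers (16 genes) were not called, both at 0.134, although fry with the block called the carriers (0.00415). Beside C3, the complement proteases C1S and C1R rose by 1.23 and 0.89 in replicates 1 and 3, and the hormone gene STC1 by 1.77, while in replicate 2 they differed by 0.13, -0.01 and -0.02.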
